A study of Homo sapiens with 12 samples.

How the data were processed

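RNA sequencing was carried out on 4 human lung adenocarcinoma cell lines, NCI-H2009, LC-2/ad, NCI-H2228 and HCC4006, each in 3 states, giving 12 libraries. Per the labels' protocols, cells were grown in RPMI-1640 medium with fetal bovine serum, detached with trypsin and put on culture plates with an ultra-low attachment surface, and RNA was taken after 1 day or 7 days. RNA of the same lines in ordinary attached culture served as the control. Total RNA was purified on RNeasy columns, and libraries were made with the SMART-Seq v4 PLUS kit, per the labels' protocols. That kit primes cDNA on the poly(A) tail and amplifies it by PCR. The submitters' processing notes name the genome build GRCh38. The aligner, the quantification tool, the annotation release and any use of strand are not given in the sources used here, so values of overlapping, antisense or near-identical genes are treated as uncertain.

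The deposited table lists 60715 genes with length-scaled transcript abundance (TPM) and an estimated count for each library, per the file headers, together with gene identifiers, coordinates, biotypes and pathway names. The TPM columns that the authors deposited each add up to 1000000. The estimated counts that the authors deposited are not normalized, and 31.5% of their values above 0 are not whole numbers. They add up to between 31134420 and 41882024 per library, so that 1 estimated count stood for about 0.0239 to 0.0321 CPM, a count scaled to the library total. PCR copies were not marked by molecular identifiers, and the totals describe counting precision only.

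The labels give each state 1 library per cell line. The 4 lines therefore served as replicates and the cell line as a block, and p-values speak of changes shared by the lines. No line has a replicate of its own in any state, so changes within a line carry no test. The pairing comes from the shared cell line. Deviations of libraries from their state's mean, across genes, correlated between states at 0.72 to 0.82 for libraries of the same line and at no more than -0.09 for libraries of different lines, in all 12 comparisons. Removing each state's mean by itself pushes the values between different lines below 0, so their sign is no result.

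Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr by state, which left 17395 genes. Libraries were scaled with TMM factors, and 1 robust quasi-likelihood model with state and cell line was fitted to the 12 libraries, leaving 6 residual degrees of freedom. The biological coefficient of variation, from the common dispersion of all genes, was 38.7%. Adjusted p is Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Fold changes are given as log2 with a standard error (SE) derived from the fold change and its quasi-likelihood F statistic. This SE therefore restates the test and is not a separate measure of spread. Mean TPM is given with the standard deviation (SD) over the 4 lines. Values of single lines are differences of log2 CPM with a prior count of 2.

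Gene lists were tested with limma 3.58.1 on log2 CPM. The 36 lists were fixed before the data were examined, and 34 of them had at least 5 measured members. The camera test with a preset inter-gene correlation of 0.01 compares a list with the other genes, and its adjusted p is over the lists of a contrast. Camera with an estimated correlation and the directional fry test, which asks whether a list's genes move on balance to 1 side, were run as alternatives. No list was past the threshold with an estimated correlation in any contrast. For changes within a line, the median of a list is given with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins.

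The rule for named genes was also fixed before the data were examined. For each detached state against attached it takes protein-coding genes past the threshold, with the same sign in the 4 lines and a mean TPM of at least 5 in the higher state, and among them the 10 largest rises and the 10 largest falls. For day 7 against day 1 it takes 5 of each. Where fewer than 5 pass, the genes with the smallest unadjusted p and the same sign in the 4 lines fill up to 5 and are said not to pass. For gene lists it takes the 2 to 4 members with the smallest p. For each line it takes the 3 genes with the largest rise and the 3 with the largest fall at day 7 relative to the mean of the other lines, on log2(TPM + 1), with a TPM of at least 10 in a library of that line. Coordinates are those of the deposited table. Some members of the lists that the rule takes are not reported here.

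The gene test was tested on simulated counts drawn from the means, library sizes and dispersions of these data. Changed genes were drawn only from genes with a mean count of at least 50, so the shares found do not cover genes with lower counts. For day 7 against attached, among 50 changed genes of each size, edgeR called 84% at 8-fold, 80% at 4-fold, 6% at 2-fold and 0% at 1.5-fold, with 5 calls among 17195 unchanged genes. DESeq2 1.42.0 called 94%, 92%, 38% and 6%, with 63 calls among the unchanged genes. The preset camera test gave an unadjusted p under 0.05 for 3 of 100 lists of unchanged, independently drawn genes.

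The alternatives were a model without the cell line block, leaving out each line in turn, fitting only the 2 states compared, no filter or a filter of TPM 5 in 4 libraries, DESeq2 size factors, quantile normalization, leaving out mitochondrially encoded and ribosomal protein genes, protein-coding genes only, DESeq2, and limma on log2(TPM + 1). After the data were examined, leaving out the NCI-H2009 day 1 or day 7 library, tests of pathway names in the deposited table and 3 further gene lists were added. Day 1 and day 7 share the attached libraries, and the association between their changes is given beside the value from 100 simulations with no change of state. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.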

Results

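Expression was measured in 4 lung adenocarcinoma cell lines in attached culture and after 1 day or 7 days without attachment. LC-2/ad carries a RET fusion, NCI-H2228 an ALK fusion and HCC4006 an activating EGFR deletion. Each state holds 4 libraries, 1 per line, with between 31134420 and 41882024 estimated counts per library. The lines kept their own transcripts in each state. ALK stood between 7.44 and 8.14 TPM in the NCI-H2228 libraries and at no more than 0.27 TPM in the others. RET stood between 11.9 and 14.4 TPM in LC-2/ad, and CDKN2A between 718 and 897 TPM in NCI-H2009. Cell line took 76.4% of the variance of log2 expression and state 9.3%.

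The first question is what differs after a day without attachment. Each line's attached library, which has no time label, was the control at both times. Effects of losing attachment therefore cannot be told apart from those of trypsin, replating or time in culture. Transcripts of mitosis were lower in the 4 lines after 1 day, together with CAV1, which codes for the main coat protein of caveolae, and with targets of the YAP and TAZ coactivators. Genes of lysosomes and of antigen presentation were higher. PLK1, a mitotic kinase, fell from 240 ± 75 TPM (SD, n = 4) to 48.2 ± 18.0 TPM, a log2 change of -2.28 ± 0.36 (SE). CAV1 fell from 403 ± 254 to 56.9 ± 26.1 TPM, a log2 change of -2.52 ± 0.45. In edgeR, 85 of 17395 genes passed, 26 of them higher and 59 lower, and each of the 85 had the same sign in the 4 lines.

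The 10 largest falls among named genes were mostly genes of cell division. They comprised the mitotic kinesins KIF14 (-2.36 ± 0.41) and KIF23 (-2.20 ± 0.37), the contractile ring protein ANLN (-2.33 ± 0.40), ARHGAP11A (-2.34 ± 0.38), the spindle protein DLGAP5 (-2.29 ± 0.39), PLK1 and the mitotic kinase PBK (-2.18 ± 0.36). FAM72D fell by 2.25 on the log2 scale, but it belongs to a family of near-identical copies and its estimated count is uncertain. P3H2, a collagen prolyl 3-hydroxylase, fell by 2.20 on the log2 scale, and CAV1 was lower in each line, between -2.98 in NCI-H2009 and -1.60 in HCC4006. CAV1 lies on chromosome 7 from 116525001 to 116561184 in GRCh38. The adjusted p of these 10 genes was 0.0496.

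The 10 largest rises are given, like the falls, among protein-coding genes with a mean TPM of at least 5 in the higher state. TMEM198 rose from 0.8 to 5.6 TPM (log2 change 2.78 ± 0.43), PLA2G4C, a phospholipase A2, from 2.8 to 15 TPM (2.68 ± 0.43) and TMEM176B from 4.7 to 20.6 TPM (2.25 ± 0.40). RRAGD, a Rag GTPase that links lysosomal nutrient sensing to mTORC1, rose by 2.11 ± 0.35, and LY96, the co-receptor of TLR4, rose from 22.0 to 75.1 TPM. EPOR, the erythropoietin receptor, rose by 1.68 ± 0.30, AMN1 by 1.74 ± 0.31 and MAGIX by 1.66 ± 0.26. The histone gene H2AC19, on chromosome 1 from 149851061 to 149851624, rose from 209 to 665 TPM (1.80 ± 0.17) with an edgeR adjusted p of 0.0157. H2AC18 is a near-identical copy of H2AC19, so their values cannot be separated with certainty. AC138894.1 (1.74 ± 0.27) overlaps CLN3 and NPIPB7 on the same strand and is uncertain for that reason. The other 9 rises had an adjusted p of 0.0496.

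**Figure D1:**
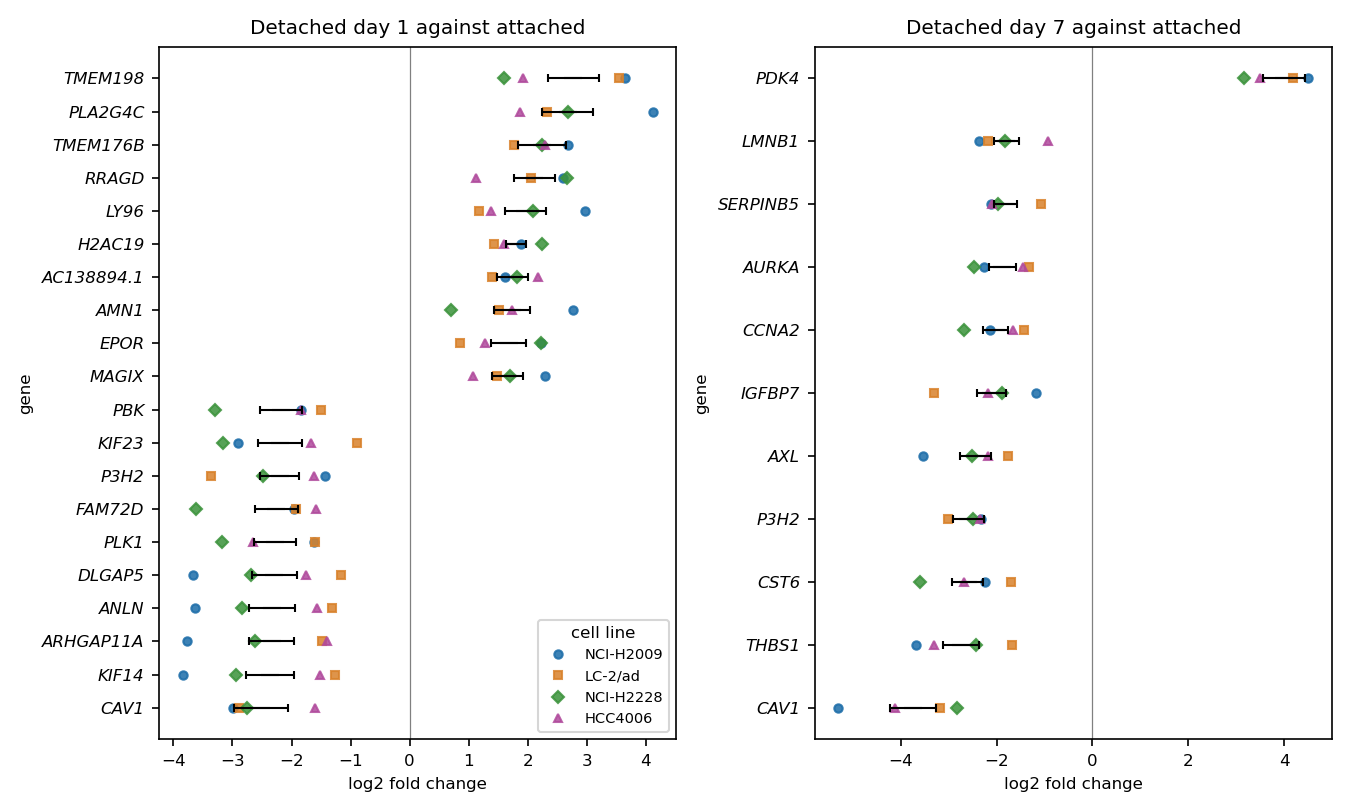
Log2 fold changes of named genes past the threshold, after 1 day (left) and 7 days (right) without attachment, against attached culture. Colored symbols are single lines, black bars are the edgeR estimate with its SE, and genes are ordered by that estimate, from CAV1 at the bottom to TMEM198 (2.78) and PDK4 at the top.

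Of the fixed lists, 12 of 34 passed at day 1 with limma's camera test. The G2/M and mitosis list fell (median -1.76, adjusted p = 1.04e-14). Of its 18 measured genes 5 fell over all genes tested and 17 fell when adjusted over the list alone; adjusted p = 0.46 with an estimated correlation. CCNA2 fell from 93.7 to 25.3 TPM, AURKA from 138 to 38.0 TPM and CCNB1 from 434 to 110 TPM, with PLK1 beside them. The list median was lower in each line, from -1.04 in LC-2/ad to -2.70 in NCI-H2228. The DNA replication and G1/S list fell with a median of -0.60 (camera adjusted p = 0.000343), with no member past the threshold over all genes and 1, UHRF1 (-1.39 ± 0.36), adjusted over the list alone; adjusted p = 0.599 with an estimated correlation. That fall rested on NCI-H2228: without that line the median was -0.19 and the adjusted p 0.17.

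Lists that concern adhesion and shape were lower. The YAP/TAZ target list fell (median -0.91, adjusted p = 7.21e-07), with AXL, a receptor tyrosine kinase, the only one of 22 genes past the threshold over all genes (25.9 to 4.7 TPM) and 10 adjusted over the list alone. AJUBA (-1.59 ± 0.30), AMOTL2 (-0.87 ± 0.21) and FJX1 (-2.41 ± 0.61) were among the latter. The actin and SRF list (median -0.50, adjusted p = 0.00111) and the integrin and focal adhesion list (median -0.42, adjusted p = 0.00112) also fell. No member passed over all genes, and adjusted over the list alone 0 of 16 and 1 of 18 did. CALD1 stood at -0.88 ± 0.26, FLNA at -1.13 ± 0.39, the focal adhesion scaffold PXN at -0.76 ± 0.16 and ITGA6 at -1.02 ± 0.33. For each of these 3 lists the adjusted p = 0.46 with an estimated correlation.

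Lysosome and autophagy genes rose as a list (median 1.01, adjusted p = 1.15e-08). None of the 18 passed over all genes and 14 rose when adjusted over the list alone, among them the sialidase NEU1 (1.80 ± 0.38), WIPI1 (1.44 ± 0.27), the lysosomal channel MCOLN1 (1.05 ± 0.24) and the protease CTSB (535 to 1166 TPM); adjusted p = 0.46 with an estimated correlation. MHC class I presentation genes rose (median 0.78, adjusted p = 0.000231), 0 of 12 over all genes and 9 adjusted over the list alone. HLA-F stood at 1.64 ± 0.38 and B2M at 0.80 ± 0.20. Hypoxia genes rose (median 0.81, adjusted p = 0.000165), 0 of 17 over all genes and 8 adjusted over the list alone, with P4HA1 at 1.05 ± 0.21 and KDM3A at 0.79 ± 0.18. For both lists the adjusted p = 0.46 with an estimated correlation.

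Unfolded protein response genes rose (median 0.61, adjusted p = 0.000343), 0 of 16 over all genes and 3 adjusted over the list alone, with DNAJB9 at 1.24 ± 0.26 and HERPUD1 at 1.10 ± 0.34. Secretory and goblet cell markers rose (median 1.40, adjusted p = 0.00112), 0 of 11 over all genes and 5 adjusted over the list alone. AGR2, a disulfide isomerase of mucin-producing cells, stood at 1.67 ± 0.37 and the antibody transporter PIGR at 3.06 ± 0.98. Without the cell line block the adjusted p of the secretory list was 0.0578. For these lists the adjusted p = 0.46 with an estimated correlation. NF-kappaB and cytokine genes rose (median 0.92, adjusted p = 0.0143), 0 of 15 over all genes and 2 adjusted over the list alone, CCL20 (3.87 ± 0.99) and NFKBIA (1.10 ± 0.31); adjusted p = 0.599 with an estimated correlation. Without NCI-H2009 the NF-kappaB list had a median of 0.67 and an adjusted p of 0.095. The adjusted p was 0.0526 without the NCI-H2009 day 1 library (median 0.87) and 0.0642 with the TPM filter (median 0.64).

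Mitochondrially encoded transcripts moved with these groups. They rose as a list (median 0.86, adjusted p = 7.45e-05), 0 of 11 over all genes and 7 adjusted over the list alone; adjusted p = 0.46 with an estimated correlation. MT-CO2 stood at 0.95 ± 0.25 and MT-ND2 at 1.21 ± 0.37. Their share of TPM went from 0.53% to 1.76% in NCI-H2228 and from 1.49% to 1.94% in HCC4006. Ribosomal protein genes did not pass (median 0.15, adjusted p = 0.484), with RPL10 at 0.47 ± 0.29. Leukocyte markers, 5 of them measured, did not pass (median 1.46, adjusted p = 0.0711), with CD14 at 1.97 ± 0.47. Their median was 2.51 in NCI-H2009, 1.04 in LC-2/ad, 1.73 in NCI-H2228 and 1.15 in HCC4006, at the percentiles 99.9, 98.4, 99.3 and 99.2 of matched random lists. The list passed without LC-2/ad (adjusted p 0.0387), without HCC4006 (0.0181) and without a filter (0.0325). Only 3 fibroblast markers were measured, too few for a test, and FAP stood at -0.36 ± 0.49.

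The gene calls at day 1 lay close to the threshold: none of the 85 passed when any 1 line was left out, without the block or with only the 2 states fitted, 2 of them passed with DESeq2 size factors and 4 without the NCI-H2009 day 7 library, and DESeq2 called 1709 genes. Without the NCI-H2009 day 1 library 0 genes passed. Other splits of the same 8 libraries called up to 18 lists with the preset correlation, against 12 here. The fry test called 5 lists (G2/M, YAP/TAZ, lysosome, integrins and mesenchymal markers) and at most 2 in other splits. For single lists, a camera p as small as the real one came in 16 of 35 splits for DNA replication and 11 for NF-kappaB. It came in 2, the real one included, for G2/M, YAP/TAZ, hypoxia, integrins and lysosome, and in 4 to 6 for the other lists that passed.

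The second question is what the cells look like after a week without attachment. The lower level of mitotic genes and of CAV1 was seen at day 7 as well, and genes of the extracellular matrix, of TGF-beta signaling and of the mesenchymal state were lower in the 4 lines. By list median, markers of secretory epithelium were higher in the 4 lines. Markers of alveolar epithelium were higher in 3 lines and stood at -0.17 in NCI-H2228. PDK4, the kinase that shuts off pyruvate dehydrogenase, rose 16-fold (n = 4, log2 SE 0.445), from a mean of 0.6 ± 0.6 TPM (SD) in attached culture. CAV1 fell from 403 to 33.7 ± 30.4 TPM, a log2 change of -3.74 ± 0.48. In edgeR 18 genes passed, 1 higher and 17 lower, and each had the same sign in the 4 lines.

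PDK4, on chromosome 7 from 95583499 to 95596516, was higher by 4.51, 4.20, 3.17 and 3.50 in NCI-H2009, LC-2/ad, NCI-H2228 and HCC4006, with an edgeR adjusted p of 0.0448. TMEM176B (2.74 ± 0.42), PCDH20 (1.82 ± 0.28), the lysosomal glucosidase GAA (49.6 to 150 TPM) and the metalloreductase STEAP4 (2.42 ± 0.39) came next and did not pass, with adjusted p between 0.0538 and 0.0555. Among the falls, THBS1, which codes for thrombospondin, went from 106 to 13.5 TPM (-2.74 ± 0.37), the protease inhibitor CST6 from 1133 to 292 TPM (-2.61 ± 0.32), P3H2 from 11.5 to 2.4 TPM (-2.59 ± 0.33), AXL from 25.9 to 5.1 TPM (-2.44 ± 0.33) and IGFBP7, a secreted binding protein, from 161 to 21.9 TPM (-2.11 ± 0.30). The cyclin CCNA2 (-2.02 ± 0.26), the mitotic kinase AURKA (-1.88 ± 0.27), the serpin SERPINB5 (-1.81 ± 0.23) and the nuclear lamin LMNB1 (-1.80 ± 0.26) completed the 10, with adjusted p from 0.0448 to 0.0474.

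Of the 34 lists, 21 passed at day 7. The G2/M and mitosis list fell (median -1.66, adjusted p = 4.01e-17), 2 of 18 over all genes and 18 adjusted over the list alone; adjusted p = 0.151 with an estimated correlation. BUB1B stood at -1.63 ± 0.28 and BUB1 at -1.60 ± 0.28, beside CCNA2 and AURKA. The DNA replication list fell (median -0.73, adjusted p = 2.81e-07), 0 of 16 over all genes and 9 adjusted over the list alone, with TYMS at -1.53 ± 0.40 and PCNA at -0.78 ± 0.22; adjusted p = 0.407 with an estimated correlation.

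YAP/TAZ targets fell (median -1.02, adjusted p = 2.16e-09), 1 of 22 over all genes (AXL) and 12 adjusted over the list alone; ANKRD1 stood at -3.68 ± 0.67 and TGFB2 at -2.39 ± 0.51. TGF-beta targets fell (median -0.82, adjusted p = 3.03e-06), 0 of 12 over all genes and 5 adjusted over the list alone. TGFBI went from 765 to 196 TPM (-1.90 ± 0.29) and ID1 from 601 to 286 TPM. Extracellular matrix genes fell (median -0.86, adjusted p = 9.28e-06). The 3 of 17 past the threshold over all genes were THBS1, the laminin chain LAMB1 (-1.79 ± 0.25) and the collagen chain COL4A2 (-1.55 ± 0.22), and 8 fell and 1 rose adjusted over the list alone. The riser was FN1, fibronectin, at 0.95 ± 0.23, higher in the 4 lines. Mesenchymal markers fell (median -0.91, adjusted p = 0.000139), 0 of 12 over all genes and 5 adjusted over the list alone, with CDH2, N-cadherin, at -2.41 ± 0.46 and MMP2 at -2.03 ± 0.60. For each of these 4 lists the adjusted p = 0.105 with an estimated correlation. The fall of the mesenchymal list was larger in LC-2/ad, at -1.99, than in the other lines, between -0.75 and -0.58, a difference with no test. At day 1 the mesenchymal list already had a median of -0.87, below 0 in the 4 lines, but did not pass with camera (adjusted p = 0.147). It passed at day 1 without NCI-H2009 (0.045) and with only the 2 states fitted (0.0454).

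The actin and SRF list fell (median -0.51, adjusted p = 9.28e-06), 0 of 16 over all genes and 6 adjusted over the list alone, with TPM2 at -1.06 ± 0.33; adjusted p = 0.339 with an estimated correlation. The integrin list fell (median -0.29, adjusted p = 0.013), 0 of 18 over all genes and 1, PXN (-0.67 ± 0.16), adjusted over the list alone; adjusted p = 0.349 with an estimated correlation. Without NCI-H2009 the integrin list had an adjusted p of 0.0598.

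Lipid synthesis genes were lower at day 7. The cholesterol list fell (median -0.77, adjusted p = 8.44e-07), 0 of 20 over all genes and 5 adjusted over the list alone, among them SQLE, an enzyme of sterol synthesis (78.8 to 26.9 TPM), and the sterol transfer protein STARD4 (-1.21 ± 0.35). The fatty acid synthesis list fell (median -0.63, adjusted p = 0.000417), 0 of 11 over all genes and 5 adjusted over the list alone, with the desaturases SCD (-1.87 ± 0.58) and FADS2 (-1.65 ± 0.49). For both lists the adjusted p = 0.407 with an estimated correlation. Glycolysis genes fell (median -0.44, adjusted p = 0.00263), 0 of 16 over all genes or adjusted over the list alone, with LDHA at -0.97 ± 0.30; adjusted p = 0.507 with an estimated correlation. Heat shock genes fell (median -0.44, adjusted p = 0.0373), 0 of 11 by either count, with DNAJB1 at -0.47 ± 0.19; adjusted p = 0.554 with an estimated correlation.

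Secretory and goblet markers rose (median 2.02, adjusted p = 1.48e-06), 0 of 11 over all genes and 7 adjusted over the list alone; adjusted p = 0.168 with an estimated correlation. The mucin MUC5B stood at 2.65 ± 0.43, PIGR at 5.13 ± 1.07 (21.7 to 322 TPM), LCN2 at 2.73 ± 0.63 (233 to 1399 TPM) and MUC16 at 2.43 ± 0.66. Alveolar type 2 markers rose (median 2.17, adjusted p = 0.000623), 0 of 9 over all genes and 5 adjusted over the list alone; adjusted p = 0.339 with an estimated correlation. The protease NAPSA stood at 2.92 ± 0.56, LAMP3 at 1.93 ± 0.54 and the phosphate transporter SLC34A2 at 4.24 ± 1.42. The alveolar list median was 2.70 in NCI-H2009, 1.78 in LC-2/ad, 1.05 in HCC4006 and -0.17 in NCI-H2228, at the percentiles 100, 100, 99.9 and 17.9 of matched random lists. At day 1 the alveolar list did not pass (median 0.67, adjusted p = 0.0934), and its median in NCI-H2228 was 1.59, at the percentile 99.9. With camera it passed at day 1 without LC-2/ad (median 0.96, adjusted p 0.0387), with only the 2 states fitted (0.0152) and with limma on log2(TPM + 1) (0.0458). Ciliated cell markers rose (median 1.99, adjusted p = 0.00649), 0 of 8 over all genes, 4 up and 1 down adjusted over the list alone; adjusted p = 0.339 with an estimated correlation. TPPP3 stood at 3.09 ± 0.91 and the tubulin TUBB4B, also used outside cilia, at -0.72 ± 0.20.

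MHC class I genes rose (median 0.73, adjusted p = 0.000871), 0 of 12 over all genes, 7 up and 1, the peptide transporter TAP2 (-0.79 ± 0.22), down adjusted over the list alone, with HLA-B at 1.44 ± 0.38 and HLA-E at 1.39 ± 0.38; adjusted p = 0.452 with an estimated correlation. Lysosome genes rose (median 0.64, adjusted p = 0.000139), 0 of 18 over all genes and 4 adjusted over the list alone, with CTSB at 1.05 ± 0.26 and HEXA at 0.91 ± 0.28; adjusted p = 0.453 with an estimated correlation. NF-kappaB genes rose (median 1.01, adjusted p = 0.00366), 0 of 15 by either count, with ICAM1 at 1.35 ± 0.53; adjusted p = 0.453 with an estimated correlation. Unfolded protein response genes rose (median 0.46, adjusted p = 0.00649), 0 of 16 by either count, with XBP1 at 0.82 ± 0.26; adjusted p = 0.452 with an estimated correlation. The NF-kappaB list median was 2.74 in NCI-H2009, 1.30 in LC-2/ad, 0.55 in HCC4006 and -0.47 in NCI-H2228, and without NCI-H2009 the list had a median of 0.49 and an adjusted p of 0.0674. Without NCI-H2228 the unfolded protein response list had an adjusted p of 0.1.

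Ribosomal protein genes fell as a list at day 7 (median -0.35, adjusted p = 0.000312), 0 of 19 by either count, with RPL5 at -0.58 ± 0.27; adjusted p = 0.554 with an estimated correlation. Their median was -1.37 in NCI-H2009, -0.56 in LC-2/ad, 0.10 in NCI-H2228 and 0.15 in HCC4006, and their share of TPM in NCI-H2009 was 3.75% at day 7 against 8.52% when attached. Without the NCI-H2009 day 7 library the adjusted p was 0.305 for ribosomal proteins, 0.126 for glycolysis and 0.202 for heat shock. Leaving out NCI-H2009 in all states gave 0.0905 for ribosomal proteins and 0.444 for heat shock, and heat shock had 0.118 without LC-2/ad, 0.0544 with the TPM filter and 0.0863 with quantile normalization. Mitochondrially encoded transcripts rose (median 0.66, adjusted p = 0.00415), 0 of 11 by either count, with MT-CO1 at 0.73 ± 0.27; adjusted p = 0.521 with an estimated correlation. The list median was 1.56 in NCI-H2228, 0.99 in HCC4006, -0.11 in NCI-H2009 and -0.14 in LC-2/ad, and without NCI-H2228 the list had a median of 0.24 and an adjusted p of 0.193. Leukocyte markers did not pass (median 0.22, adjusted p = 0.411), with CD14 at 1.67 ± 0.48. Their median was 2.15 in NCI-H2009, 0.08 in LC-2/ad, 0.00 in NCI-H2228 and 2.18 in HCC4006, at the percentiles 99.5, 59.8, 42.1 and 99.9 of matched random lists, and the fibroblast marker FAP stood at -2.49 ± 0.54.

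**Figure D2:**
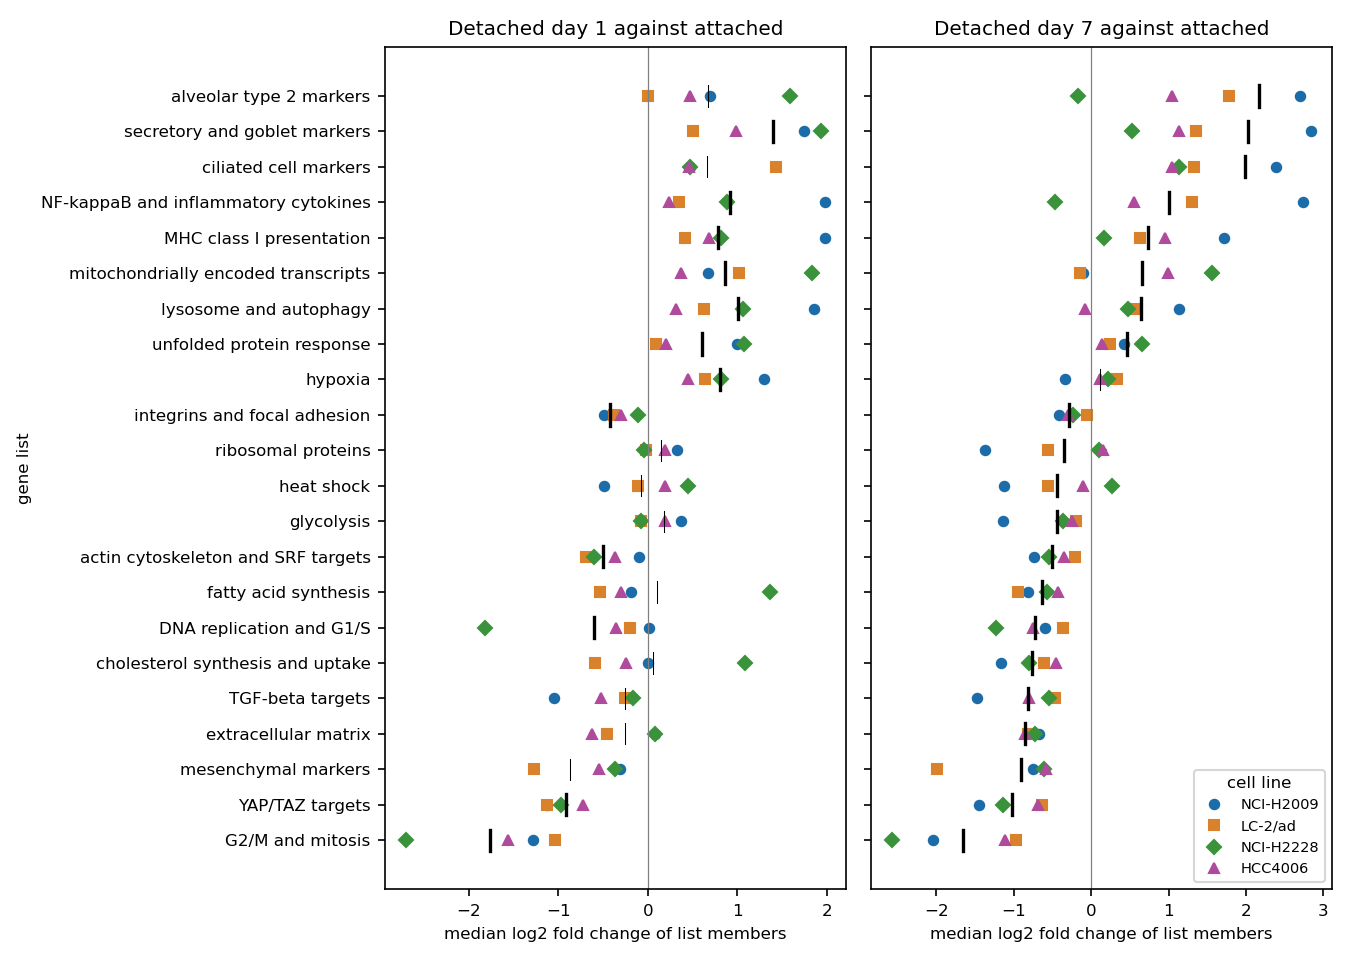
Median log2 fold change of gene lists that passed at day 1 or day 7, against attached culture. Symbols are the medians of single lines, and black ticks are the medians of edgeR estimates, thick where the camera test with the preset correlation passed; the G2/M list lies at -1.76 and -1.66 and the secretory list at 1.40 and 2.02.

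At day 7 the number of genes called was 0 without NCI-H2009, NCI-H2228 or HCC4006 and 1, outside the 18, without LC-2/ad, 0 without the block or without the NCI-H2009 day 7 library, 6 with DESeq2 size factors, 30 with quantile normalization and 1162 with DESeq2. Without the NCI-H2009 day 1 library it was 69, all 18 among them. Another split of these 8 libraries called as many lists with the preset correlation (21). The fry test called 6 lists (G2/M, YAP/TAZ, TGF-beta, extracellular matrix, mesenchymal and secretory) and 0 in each other split. A camera p as small as the real one came in 17 of 35 splits for ribosomal proteins and 15 for heat shock. It came in 12 for NF-kappaB, 12 for mitochondrial transcripts and 11 for glycolysis. For the 6 lists that fry called and for ciliated markers it came in 1 or 2, the real one included. For the other lists that passed it came in 4 to 7.

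Changes at day 1 and at day 7 were related across genes. Of the 59 genes that fell at day 1 and the 17 that fell at day 7, 10 were shared, against 0.1 for independent lists, a value that makes no allowance for the attached libraries in common, and PDK4 was the gene higher at both times. The mean changes of the 4 lines correlated at r = 0.65 across genes, which are not independent replicates. Because both use the same attached libraries, simulations with no change of state gave r = 0.50, and the covariance was 0.316 against 0.106 in simulations. With the day 1 change taken from 2 lines and the day 7 change from the other 2, r lay between 0.27 and 0.45. This covers 6 ways of dividing the lines and compares means of different lines, so it is not on the same footing as r = 0.65.

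The third comparison asks what separates a week from a day without attachment. No gene passed in edgeR, which had 1702 genes at an unadjusted p under 0.05. Other splits of the same libraries had up to 2056 such genes (median 546), and up to 1564 where every line's libraries were parted. DESeq2 called 193 genes and limma on log2(TPM + 1) 0. Genes of cholesterol and fatty acid synthesis, hypoxia and TGF-beta targets were lower at day 7 than at day 1, by amounts that differed between the lines. The list medians ran from -1.76 in NCI-H2228 to -0.15 in HCC4006 for cholesterol and from -1.51 to -0.02 in the same lines for fatty acid synthesis. They ran from -1.42 in NCI-H2009 to -0.09 in LC-2/ad for hypoxia and from -0.95 in NCI-H2228 to -0.16 in LC-2/ad for TGF-beta targets. The genes closest to the threshold were lower H2AC19 (-1.22 ± 0.17), the TGF-beta target ID2 (91.2 to 29.7 TPM, -1.69 ± 0.25), IGFBP7 (-1.90 ± 0.30), TMEM45A (-3.02 ± 0.48) and CST6 (-1.95 ± 0.31), each with an adjusted p of 0.259. Higher at day 7 were VPS4A (0.99 ± 0.16), AC026464.4 (1.09 ± 0.17), ZNF496 (1.29 ± 0.22), NEBL (1.44 ± 0.26) and TTC4 (1.09 ± 0.20), with adjusted p from 0.259 to 0.341. AC026464.4 overlaps VPS4A on the same strand, TTC4 overlaps a read-through gene, and their estimated counts are uncertain.

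Camera passed 11 of 34 lists between day 7 and day 1. The cholesterol list fell (median -0.85, adjusted p = 6.37e-08), 0 of 20 over all genes and 10 adjusted over the list alone, with INSIG1 at -2.26 ± 0.60 and MVD at -0.97 ± 0.23; adjusted p = 0.608 with an estimated correlation. Hypoxia genes fell (median -0.69, adjusted p = 7.48e-05), 0 of 17 over all genes and 3 adjusted over the list alone, with P4HA1 at -0.94 ± 0.21; adjusted p = 0.608 with an estimated correlation. Fatty acid synthesis fell (median -0.55, adjusted p = 0.000653), 0 of 11 and 5 adjusted over the list alone, with SCD at -2.21 ± 0.61, and glycolysis fell (median -0.54, adjusted p = 7.48e-05), 0 of 16 and 1, ALDOC (-2.03 ± 0.43), adjusted over the list alone. For both the adjusted p = 0.625 with an estimated correlation. TGF-beta targets (median -0.78, adjusted p = 0.000653), extracellular matrix genes (median -0.58, adjusted p = 0.00101) and mesenchymal markers (median -0.37, adjusted p = 0.0391) fell, with 0 members over all genes and 5, 0 and 0 adjusted over the list alone. ID1 stood at -1.32 ± 0.24, COL4A2 at -0.60 ± 0.22 and SNAI1 at -1.96 ± 0.59; adjusted p = 0.444 with an estimated correlation for the 3 lists.

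The MAPK output list rose (median 0.52, adjusted p = 0.0016), 0 of 18 over all genes and 1, the ETS factor ETV4 (1.57 ± 0.30), adjusted over the list alone, with DUSP6 at 0.73 ± 0.36; adjusted p = 0.608 with an estimated correlation. The lysosome list fell (median -0.37, adjusted p = 0.0013), 0 of 18 by either count, with LAMP1 at -0.59 ± 0.20, and ribosomal proteins fell (median -0.51, adjusted p = 3.1e-06), 0 of 19 by either count, with RPL10 at -0.71 ± 0.30. For both the adjusted p = 0.715 with an estimated correlation. The ribosomal list median was -1.65 in NCI-H2009, -0.64 in LC-2/ad, -0.05 in HCC4006 and 0.10 in NCI-H2228. Nuclear-encoded respiratory chain genes fell (median -0.24, adjusted p = 0.0098), 0 of 16 by either count, with ATP5PO at -0.45 ± 0.19; adjusted p = 0.724 with an estimated correlation. Mitochondrially encoded transcripts did not pass (median -0.38, adjusted p = 0.0582), with MT-CO2 at -0.68 ± 0.25. They passed without the block (0.0373), without NCI-H2228 (0.0442) or HCC4006 (0.00181), with only the 2 states fitted (0.0374), without a filter (0.0266) and with limma on TPM (0.0383). Leukocyte markers did not pass (median -0.41, adjusted p = 0.177), with CSF1R at -1.55 ± 0.71, but passed without HCC4006 (0.0162) and with only the 2 states fitted (0.0448), and the fibroblast marker FAP stood at -2.12 ± 0.53. The respiratory chain list had an adjusted p of 0.654 without NCI-H2009, 0.327 without its day 7 library, 0.169 with quantile normalization and 0.0969 with limma on TPM, and the mesenchymal list 0.248 without the block (median -0.42), 0.0778 without LC-2/ad (-0.33), 0.0548 without HCC4006 (-0.44) and 0.0513 with the TPM filter (-0.52). Without the NCI-H2009 day 1 library the adjusted p was 0.0998 for the lysosome list, 0.325 for the respiratory chain list and 0.0543 for the mesenchymal list (median -0.53). Alveolar markers did not pass with camera (median 1.34, adjusted p = 0.0829). They passed without NCI-H2228 (median 2.05, adjusted p 0.000294), with only the 2 states fitted (0.0308) and without a filter (0.0184). Secretory (0.00571) and ciliated markers (0.0442) also passed without NCI-H2228. The fry test called 0 lists here, and other splits of the libraries called up to 17 with the preset correlation. A camera p as small as the real one came in 14 of 35 splits for respiratory chain genes. It came in 11 for ribosomal proteins and 10 for the lysosome list. For TGF-beta targets and mesenchymal markers it came in 1, the real one, and for extracellular matrix genes in 2. For the other lists that passed it came in 4 to 7.

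The fixed lists that passed in no contrast were p53 targets, epithelial junctions and keratins, ATF4 and amino acid response, NRF2 targets, interferon-stimulated genes, the pro-apoptotic BCL2 family, receptor tyrosine kinases, stem cell-associated genes, basal and squamous markers and leukocyte markers, with neuroendocrine and fibroblast markers too sparsely measured for a test. Of these, p53 targets, ATF4 and amino acid response, NRF2 targets, interferon-stimulated genes, receptor tyrosine kinases and leukocyte markers passed in some contrast under at least 1 alternative. Among the lists that passed, the median, the mean and the test had the same sign.

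The lines differed in how far and where they moved, with 1 library per line and state and therefore no replicate check. In NCI-H2009, 3904 genes were 2-fold apart at day 1 among those with a TPM of at least 5 in either library, and 3460 at day 7. Of these, 1129 were higher and 2775 lower at day 1, against 2452 higher and 1008 lower at day 7. These counts are TPM ratios without TMM scaling. The TMM factors of this line were 1.088 attached, 0.909 at day 1 and 1.121 at day 7, and how far scaling enters the directions was not tested. The day 1 library of this line stood apart, with the fewest genes at a TPM of at least 1 (13464), the shortest median gene length weighted by counts (2723 nucleotides) and 9.96% of counts in its 10 most abundant genes. The numbers of genes 2-fold apart were 801 and 1063 in LC-2/ad, 2055 and 1219 in NCI-H2228, and 703 and 1079 in HCC4006. Across genes, changes correlated between lines at r = 0.27 to 0.32 at day 1 and 0.14 to 0.38 at day 7, and 33.7% and 28.4% of genes had the same sign in the 4 lines, where independent signs give 1 in 8. Within a line, day 1 and day 7 correlated at r = 0.50 in NCI-H2009, 0.49 in LC-2/ad, 0.53 in NCI-H2228 and 0.55 in HCC4006, against 0.50 in simulations with no change of state. The covariances were 0.934, 0.413, 0.521 and 0.408, against 0.429, 0.409, 0.434 and 0.432 in the simulations. The simulations used 1 dispersion per gene for the 4 lines, from a fit that counts line-specific changes as spread. The simulated covariances are therefore no baseline for a single line.

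By the rule for single lines, 17 of 24 entries were not protein-coding, with lengths under 200 nucleotides, and their highest estimated counts lay between 1 and 13.6, too few to read as changes. The 7 protein-coding entries were SLC34A2 in NCI-H2009 (0.483 to 372 TPM), CYP1A1 in LC-2/ad (15.5 to 840 TPM), a xenobiotic-metabolizing enzyme, NNMT in LC-2/ad (82.6 to 2.87 TPM), PLAT (568 to 37.8 TPM), CCL2 (248 to 8.41 TPM) and SLC34A2 (575 to 395 TPM, with 2680 TPM at day 1) in NCI-H2228, and BPIFB2 in HCC4006 (1.98 to 218 TPM). With the rule held to protein-coding genes, a choice made after the values were seen, the highest in NCI-H2009 also included the defensin DEFB4A (69.6 TPM at day 7) and HOPX (0.501 to 83.9 TPM), an alveolar type 1 marker. LC-2/ad also had ANGPTL4 (23.4 TPM at day 7) and CEACAM6 (17.8 to 783 TPM), and HCC4006 the salivary-type cystatins CST1 (271 to 7960 TPM) and CST4 (406 to 14300 TPM), close relatives whose counts can be shared.

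**Figure D3:**
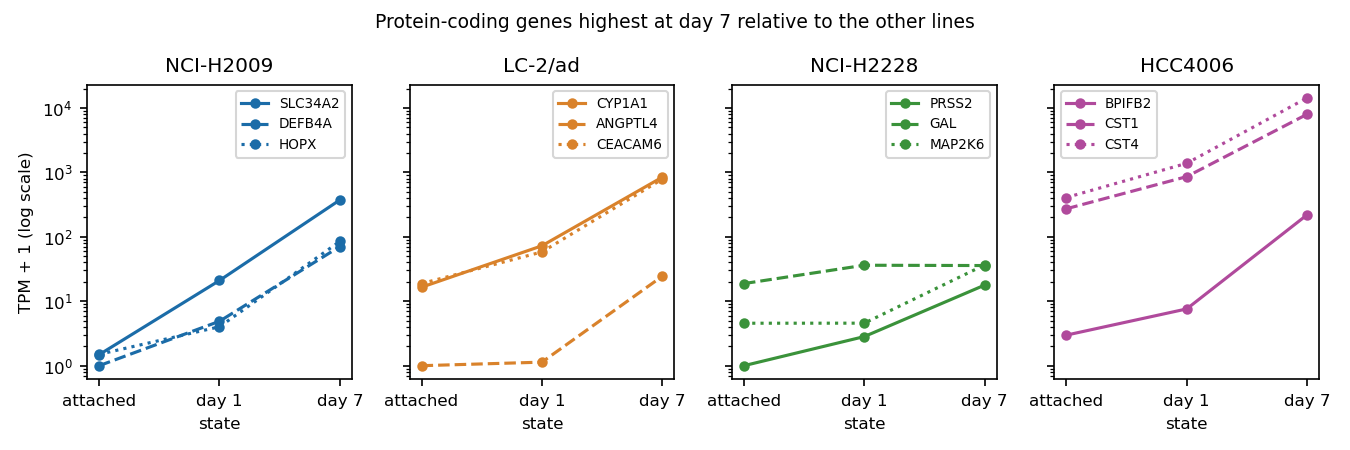
TPM + 1 on a log axis in the attached, day 1 and day 7 library of each line, for the 3 protein-coding genes highest at day 7 relative to the other lines. Each point is a single library; SLC34A2 in NCI-H2009 goes from 0.483 to 372 TPM and CST4 in HCC4006 from 406 to 14300 TPM.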

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

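The tests of the most abundant genes, of scaling, of nuclear RNAs, of respiratory chain genes, of foreign RNA and of list counts over other splits were chosen after the result was seen. Among 108 groups of 4 lines examined, 6 had a line far from the other 3, where chance gives about 1 in 20. CAV1 at day 1 was least lowered in HCC4006, at -1.60, next to -2.75 in NCI-H2228. SERPINB5 at day 7 was least lowered in LC-2/ad, at -1.07, next to -1.98. TTC4 between day 1 and day 7 stood at 1.65 in NCI-H2009, next to 0.97. The mesenchymal list at day 7 stood at -1.99 in LC-2/ad, next to -0.75. The respiratory chain list between day 1 and day 7 stood at -0.82 in NCI-H2009, next to -0.10. NCI-H2009 had 3460 genes 2-fold apart at day 7, next to 1219 in NCI-H2228.

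The effects of day 7 and day 1 differed by limma's camera test, with the preset correlation, for 11 lists. The adjusted p was 6.37e-08 for cholesterol synthesis, 3.1e-06 for ribosomal proteins, 7.48e-05 for hypoxia and for glycolysis, 0.000653 for fatty acid synthesis and for TGF-beta targets, 0.00101 for extracellular matrix, 0.0013 for lysosome, 0.0016 for MAPK output, 0.0098 for respiratory chain genes and 0.0391 for mesenchymal markers. None of them passed with an estimated correlation.

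Ribosomal protein transcripts were lower in the NCI-H2009 day 7 library, with a median of -1.37 and 19 of 19 genes lower. A few genes taking the counts is argued against, since the share of the 10 most abundant genes differed by -0.03 percentage points from the attached library. A loss of short or abundant transcripts in this library cannot be told apart from a change in these genes. A set of 139 other genes matched on length and attached expression had a median of -0.75, with quartiles of -1.10 and -0.20. That median lay between the bounds of -0.9 and -0.7. The bounds were set before the matched genes were compared, but the second came from the ribosomal median already seen. A change of state in this line stays open and untested, because it rests on 1 library.

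Mitochondrially encoded transcripts were higher at day 1 in the 4 lines. The choice among 4 scalings is argued against, since the lowest median over them was 0.75. All 4 are relative to the other transcripts, so they cannot show a change in total RNA per cell. Leaking cells that keep nuclei and mitochondria would raise nuclear-retained RNAs as well. The 7 of these measured had a median of -0.22 over genes and lines. It was -1.04 in NCI-H2009, -0.42 in LC-2/ad and -0.04 in HCC4006, but 0.33 in NCI-H2228, where the mitochondrial rise was largest (1.83). The lowest value comes from the NCI-H2009 day 1 library, which stood apart in gene length and genes detected. Leaking therefore cannot be judged in that line and stays open in NCI-H2228. More mitochondria per cell would raise nuclear-encoded respiratory chain genes, and these had a median of 0.08, with quartiles of 0.00 and 0.15. Altered synthesis or stability of mitochondrial RNA, and its capture by poly(A) priming, were not tested and stay open.

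Alveolar and secretory genes were higher in NCI-H2009 at day 7, with SLC34A2 at 372 TPM against 0.483 TPM attached. RNA of another line is argued against. Genes abundant in another line and silent in attached NCI-H2009 reached a median of 1.16% of their level in LC-2/ad, 0.185% in NCI-H2228 and 0.247% in HCC4006, where SLC34A2 would need 30.6% of NCI-H2228 or 28.8% of HCC4006 and more than LC-2/ad holds. CDKN2A stood at 844 TPM in this library and at no more than 0.83 TPM in the other lines, which argues against a library of another line under this label. A change of state is the hypothesis left open, with 1 library behind it.

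Calls were counted over the 35 splits of the 8 libraries of a contrast into 4 and 4, the real one included. For the 85 genes at day 1, 1 split, the real one, gave as many, and the highest other gave 0. For the 18 genes at day 7 it was also 1, and the highest other gave 1. The libraries are paired by line, and most of these splits keep both libraries of some lines together, so the fitting comparison is with the 8 splits that part every line's libraries as the real one does. These are too few for a share under 0.05; among them the highest other counts were 0 and 1. For day 7 against day 1 all 35 splits gave at least the 0 genes called by edgeR, beside 1702 at an unadjusted p under 0.05 and 193 called by DESeq2. At that unadjusted p in edgeR the highest other split gave 2056 genes, and the highest other of the 8 gave 1564. With the preset correlation, 17 of 35 splits gave at least 12 lists at day 1 (highest other 18) and 18 gave at least 11 for day 7 against day 1 (highest other 17), and among the 8 splits 5 and 4 did, so chance cannot be excluded for these counts. At day 7, 2 of 35 gave at least 21 lists (highest other 21), and among the 8 the real one alone did (highest other 19). Chance cannot be excluded for this count either, since 8 splits are too few for a share under 0.05. With fry, the real split alone gave 5 lists at day 1 (highest other 2) and 6 at day 7 (highest other 0).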

How the results depend on the processing

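The alternatives were fixed before the data were examined, except leaving out the NCI-H2009 day 1 or day 7 library, chosen after seeing the data. The number of genes called moved by more than 1.5 times under many of them, and the cause was not tested. For day 1, day 7 and day 7 against day 1 in that order, the model called 85, 18 and 0 genes. Without the cell line block it called 0, 0 and 0, without 1 line at a time 0 to 0, 0 to 1 and 0, with only the 2 states fitted 0, 1 and 0, without a filter 265, 114 and 6, with the TPM filter 159 at day 1, with DESeq2 size factors 2 and 6, with quantile normalization 30 at day 7, with protein-coding genes 28 at day 7, with DESeq2 1709, 1162 and 193, with limma on log2(TPM + 1) 225 at day 1 (44 of them higher), and without the NCI-H2009 day 7 library 4 and 0. Without its day 1 library it called 0, 69 (19 of them higher) and 0. DESeq2 kept all 85 and all 18 genes, with 949 of 1709 and 600 of 1162 higher, where the model had 26 of 85 and 1 of 18 higher. Higher genes were 115 of 265 and 30 of 114 without a filter, 64 of 159 with the TPM filter, 1 of 2 at day 1 and 1 of 6 at day 7 with size factors, and 5 of 30 with quantile normalization. With limma on log2(TPM + 1) the median of all genes was 0.134 between day 7 and day 1, against 0.02 in the model, and -0.081 at day 1, against 0.008.

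The number of lists called, 12, 21 and 11, was 0, 0 and 0 with an estimated correlation and 5, 6 and 0 with fry. Leaving out a line gave 13 to 15, 17 to 23 and 10 to 19, the highest for day 7 against day 1 without NCI-H2228 (19). Leaving out the NCI-H2009 day 1 library gave 13, 23 and 9, and the other alternatives stayed within 1.5 times. Without the block the calls of the secretory list at day 1 (adjusted p 0.0578) and the mesenchymal list between day 7 and day 1 (0.248) were lost, p53 targets (0.0246) and respiratory chain genes (0.0409) passed at day 7, ciliated markers and mitochondrial transcripts (0.0373 each) passed between day 7 and day 1, and no other list changed its call. No named gene, and no list in a contrast where it had passed, turned its direction. Among lists in contrasts where they had not passed, the direction of the camera test turned for NRF2 targets between day 7 and day 1, from down (median 0.10, adjusted p 0.838) to up without NCI-H2009 (median 0.33, 0.037) or its day 7 library (0.0483), with the median above 0 in each of these fits. Cholesterol synthesis at day 1 went from higher (0.901) to lower without NCI-H2228 (median -0.32, 0.0299). Ribosomal proteins at day 1, which did not pass (median 0.15), lay between -0.16 without the NCI-H2009 day 1 library and 0.23 without LC-2/ad, and passed in neither. Genes 2-fold apart at day 1, with a TPM minimum of 1 and of 20, numbered 6222 and 2091 in NCI-H2009, 2181 and 341 in LC-2/ad, 3645 and 1175 in NCI-H2228, and 2018 and 288 in HCC4006. At day 7 they numbered 5761 and 1960, 2455 and 457, 2638 and 625, and 2557 and 484. Other pseudocounts and limma without moderation had been planned for a table of TPM alone and were not run. In simulations of this design edgeR found 6% of 2-fold changes among well-counted genes, so most shared changes of that size or smaller can go uncalled.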

Other observations

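The tests in this part were chosen after the data were seen. For both hypotheses, the demand that a list pass with an estimated correlation as well was added after its first p was known. MHC class II genes, present on alveolar type 2 cells as well as on antigen-presenting cells, were not among the fixed lists. At day 7 the log2 change of the invariant chain CD74 was 1.69 ± 0.41 and that of HLA-DRA 2.32 ± 0.64 (SE, n = 4), and CIITA, the class II transactivator, stood at 0.92 ± 0.34. None of the 12 passed over all genes in edgeR. The median of the 12 was 3.61 in HCC4006, 2.20 in NCI-H2009, 0.74 in LC-2/ad and 0.23 in NCI-H2228. Leukocyte markers had medians of 2.18, 2.15, 0.08 and 0.00 in these lines. The class II list was already higher at day 1, with a median of 1.5 in HCC4006, 1.52 in NCI-H2009, 0.96 in LC-2/ad and 1.32 in NCI-H2228. HLA genes are near-identical to each other in part, and their counts are uncertain. The cell surface antigen CEACAM5 went from 3.52 to 1680 TPM in NCI-H2009 and from 30.4 to 290 TPM in HCC4006, and the complement factor CFB from 1.36 to 134 TPM and from 13.0 to 220 TPM, with edgeR adjusted p of 0.11 and 0.139 over the 4 lines.

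Pathway names in the deposited table gave 51, 37 and 15 of 303 pathways past the threshold at day 1, day 7 and day 7 against day 1 with limma's camera test, and 0, 0 and 0 with an estimated correlation. At day 1 lysosome (median 0.60, adjusted p = 2.8e-10) and antigen processing and presentation (median 0.78, adjusted p = 4.22e-05) were higher and cell cycle lower (median -0.36, adjusted p = 1.12e-06); adjusted p = 0.704 with an estimated correlation for the 3. At day 7 DNA replication (median -0.54, adjusted p = 3.38e-09) and spliceosome (median -0.27, adjusted p = 5.02e-07) were lower; adjusted p = 0.765 with an estimated correlation.

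A hypothesis is that MHC class II genes moved together at day 7. Camera with the preset correlation gave an unadjusted p of 2.63e-07 at day 7 and of 0.000133 at day 1. With an estimated correlation the p was 0.107 at day 7 and 0.21 at day 1. Members had also been seen before the list was written, so the question stays open. A second hypothesis is that genes of lipid oxidation under PPAR control rose with PDK4. In LC-2/ad, ANGPTL4 was listed at 0 TPM attached and at 23.4 TPM at day 7, and CPT1A, the gate of mitochondrial fatty acid import, was higher by 4.55. In HCC4006, ANGPTL4 stood at -0.26, CPT1A at -0.78 and PLIN2 at -0.31. Without ANGPTL4, CPT1A and PDK4, the other 11 genes of the list, PLIN2 among them, had a median of 0.35 and an unadjusted camera p of 0.0218, and 0.256 with an estimated correlation, which leaves it open too. Over the 4 lines PLIN2 stood at 1.12 ± 0.37 and SLC25A20 at 0.80 ± 0.28, while HADHA stood at -0.16 ± 0.16.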
